A study of Bos taurus with 16 samples.

How the data were processed

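The series measured kidney RNA of cattle (Bos taurus) on a custom 2-colour cDNA array. Per the labels, RNA was isolated with Trizol, and target was made by reverse transcription with Superscript III in the presence of amino-allyl dUTP, to which the dyes Cy3 and Cy5 are coupled. There were 8 kidney RNAs. They are replicates 1 and K of unamplified total RNA (round 0) and of RNA amplified linearly once or more, called rounds 1, 2 and 3. Each was hybridised on 2 arrays of opposite dye (a dye swap) against a common reference RNA, itself amplified for 2 rounds per the labels, which gave 16 arrays. The labels do not say whether replicates 1 and K are separate animals or separate amplifications of 1 RNA.

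The deposited values of 15 arrays are log2 ratios of the 2 channels. In the column of the round 1, replicate 1, Cy3 array, deposited values that are mostly such ratios stand beside 52 numbers outside their range, from -26 to 3827, so that the column as a whole is called a score. Its numbers up to 10 in size were used as log2 ratios like those of the other arrays, and the 52 as missing. The scanner, image software, background correction and normalization by the authors are not given in the sources used here. The deposited ratios run by dye: the arrays of a dye swap correlated negatively across spots (Pearson r from -0.678 to -0.245). They are not centred, since array medians ranged from -2.30 to 0.08. The number 16.61 recurred in 22 to 172 spots per array as a code for an undefined ratio. It and every other number beyond 10 in size were treated as missing.

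The array carried 16896 spots, read as 8448 features (spotted cDNA clones) printed as duplicates and averaged here. The annotation table lists a gene for 5693 features, 5598 of them with 1 symbol, and leaves 2755 without a gene. Symbols were compared through gene identifiers with a current gene table, and all 5591 found there were the same. Arrays with kidney in Cy3 were turned so that every value is kidney over reference, each array was centred on the median of the listed features, and the dye swap of each RNA was averaged. Whether Cy5 stands over Cy3 in the deposited ratios is not stated; it was taken as likely because the median of the kidney gene list was then near 2 in both dye orientations at round 0. The sign of that list against the reference is therefore a choice and not a result. Tests used the 5537 listed features with a value in both replicates of every round, for 4360 genes; features without a listed gene were left out because control spots cannot be told from clones among them. That restriction was chosen after seeing the data.

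Depth on an array is the share of spots with a ratio, 83.9% to 95.0% here, and the number of arrays limits the precision. No signal intensities were used, so that dim spots could not be filtered and no intensity-dependent correction was made. Transcript length and GC content were not analysed here for lack of a table, and no genome positions were used.

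Rounds were compared with limma 3.58.1 in R 4.3.3 with data.table version 1.17.8, by lmFit and eBayes with a mean for each round, 4 residual degrees of freedom and 2.4 prior ones. Because n = 2 per round, the spread is pooled over rounds, and the p-values measure only the spread between these RNAs. P-values were adjusted by Benjamini and Hochberg over all tested features, with a threshold of 0.05. All 6 pairs of rounds were compared, a moderated F test asked for any difference among rounds, and the mean ratio at each round was tested against 0. No exact test with 2 against 2 samples can pass 0.05, and correlations across features carry no p because features are not independent replicates. The replicate numbers were not shown to pair samples across rounds: residuals of replicate 1 correlated above 0.1 between rounds in 1 of 6 pairs of rounds.

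Gene lists were fixed before the data were examined. They hold markers of kidney, placenta, immune cells, blood and stroma. Families were cytosolic and mitochondrial ribosomal proteins, mitochondrially encoded genes, oxidative phosphorylation, proteasome, translation factors, chaperones, histones, splicing factors, reference genes with the cytoskeleton, and immediate early or stress genes. The blood and mitochondrially encoded lists had 0 tested features, which left 14 lists. Lists were tested with camera at a preset correlation of 0.01, then with an estimated correlation, and with fry, each adjusted over the lists of a comparison. List members were also counted when adjusted over the list alone.

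The rule for named genes was set before the data were examined. Against round 0 it takes, among features with 1 symbol, an adjusted p under 0.05 and no overlap between the replicates of the rounds, the 10 largest increases and the 10 largest decreases. Between amplified rounds it takes the 3 largest each way, or, where fewer than 5 pass, the 3 with the smallest p, said not to pass. From each list it takes the 2 largest called changes each way, or the 2 smallest p if none is called. The 12 genes named for their ratio to the reference at all rounds, and the features named beyond 3 per direction between rounds 3 and 1, were chosen after seeing the data.

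The pipeline was tested on simulated data of the same size with 200 changed features. At rounds 1, 2 and 3 against round 0, limma recovered 91%, 88% and 90% of changes of 3 on the log2 scale. It recovered 1%, 4% and 8% of changes of 1, so that the counts cover large changes. Of 101, 100 and 104 calls, 9, 8 and 6 were false. Shared changes and shared calls between comparisons were set beside 100 simulations of unchanged groups, intervals for clone pairs used 1000 bootstrap samples, and the kidney list was compared with 10000 random lists. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.

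Several alternatives were set before the data were examined. For the values these were no centring, scaling to 1 median absolute deviation, quantile normalization, and other filters on missing values and small ratios. For the fit they were a replicate block, all arrays with a dye term, each dye orientation alone, only the rounds compared, a trended robust prior, stricter thresholds and leaving out each replicate. Other measures of correlation and spread and other list tests were run too. Alternatives added after seeing the data were all 8448 features, leaving out the round 1, replicate 1, Cy3 array, the features whose duplicate spots differ least, both rescalings for the gene lists, and an estimated correlation for the lists without centring.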

Results

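The data are 16 arrays of cattle kidney RNA, hybridised as dye swaps against 1 reference RNA. They hold 2 replicates (1 and K) at each of 4 rounds: round 0 is unamplified total RNA, and rounds 1, 2 and 3 are the numbers of linear amplifications. Between 14182 and 16057 of the 16896 spots on an array had a ratio, and duplicate spots of an array correlated at 0.541 to 0.868. Each value is a log2 ratio of kidney over reference, centred on the median of its array. That direction is likely rather than stated: it was chosen so that the kidney gene list lies above the reference. If it ran the other way, every sign would turn, and each count of higher features would be one of lower features. Linear amplification copies RNA through in vitro transcription, and the series title places the work as a check of such amplification for single bovine embryos. Since the reference was amplified for 2 rounds, round 0 alone sets unamplified kidney against amplified reference.

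Among features called on 1 side of the reference at all 4 rounds, the farthest above it was ENPEP, the aminopeptidase A of the kidney brush border. Its ratio was 5.58 ± 0.04 (SD, n = 2) at round 0 and 5.22 ± 0.12, 5.35 ± 0.05 and 5.22 ± 0.37 at rounds 1, 2 and 3. AQP1, the water channel of the proximal tubule, stood at 4.44, 5.01, 4.59 and 4.16, and S100G, a vitamin D-dependent calcium-binding protein, at 5.09, 4.44, 4.53 and 4.21. GATA3, a transcription factor of kidney development, MGP of the stroma list, an inhibitor of calcification (5.72, 3.85, 4.34 and 3.62), and ABCA1, a cholesterol exporter, also stayed above 3 on the log2 scale at each round. Farthest below it, by the mean of the 4 rounds, was TCAM1 at -6.38, -4.82, -5.82 and -5.36. PCLAF (-4.56, -4.11, -4.65 and -4.67) and ANKRD1 (-4.21, -4.09, -4.34 and -3.94) came next. The metalloproteinase inhibitor TIMP1 followed at -4.79, -3.05, -3.46 and -3.51. LGALS3 (galectin) stood at -3.91, -3.46, -3.72 and -3.71, and VIM (vimentin) at -3.92, -3.51, -3.67 and -3.51.

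The kidney gene list (20 features of 13 genes) had median ratios of 2.01, 2.40, 1.59 and 1.46 at rounds 0 to 3. The median change per feature was -0.28 from round 0 to 1, against the rise of the list median, and -0.15 from round 1 to 3. The sign of the list medians is no finding, since this list set the direction of the ratio. Of its features, 15, 13, 12 and 12 passed at adjusted p under 0.05 on that side, and 0, 0, 1 and 0 on the other. Of 56 cytosolic ribosomal protein features, 43, 49, 44 and 37 passed on the side opposite to the kidney list, and 0, 0, 1 and 1 on its own side. Past the limma test were 2142 features at round 0 (1088 above, 1054 below), 2092 at round 1, 1948 at round 2 and 1942 at round 3; without centring, round 0 had 1782 above and 192 below. Of the round 0 calls, 1087 (50.7%) recurred with the same sign at round 1, 1058 at round 2 and 1054 at round 3, against 404, 376 and 375 for calls made independently, and 108, 88 and 81 were called with the opposite sign. Recurrence was 69.2% from round 1 to 2, 76.4% from round 2 to 3 and 59.6% from round 1 to 3, where 37 were called with the opposite sign. With 1 sign at all 4 rounds there were 804 features, and 36 had 1 sign at round 0 and the other at rounds 1, 2 and 3. These counts leave out the spread of the reference, and they moved with single RNAs. Round 0 had 1047 calls without its replicate 1 and 977 without replicate K. Round 1 had 1161 without K, round 2 had 1164 without 1 and 861 without K, and round 3 had 1132 and 885.

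Round 1 against round 0 asks what a single amplification did to the ratios. The feature of CFL1 (cofilin, which severs actin filaments) went from -1.51 at round 0 to 3.66 at round 1, a log2 difference of 5.17 ± 0.21 (SE, n = 2, adjusted p = 0.000734). HADHA, of the mitochondrial trifunctional protein of fatty acid oxidation, rose by 4.75 and SPPL2A, an intramembrane protease, by 4.45. PGLS, an enzyme of the pentose phosphate pathway, fell by 4.93 ± 0.26, from 5.44 to 0.51 (adjusted p = 0.00122). H19, an imprinted noncoding RNA, fell by 4.49 ± 0.20 from 4.62 to 0.13 (adjusted p = 0.000785).

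Further increases at round 1 were those of IRF2BP2, a transcriptional corepressor (3.80), the ephrin EFNA5 (3.78) and MARCKS, a substrate of protein kinase C (3.74). Next came ARHGAP17 (3.74), ECI2, an isomerase of fatty acid oxidation (3.55), GALT of galactose metabolism (3.54) and the proteoglycan FMOD (3.35). The largest decreases after PGLS and H19 were RABGAP1, which acts on Rab GTPases (-4.11), the calpain relative CAPN6 (-4.05), the sulfate transporter SLC26A2 (-3.97) and the secreted glycoprotein STC1 (-3.86). They were followed by IGFBP3, which binds insulin-like growth factors (-3.78), the lectin CLEC18C (-3.65), the AP-1 subunit FOSB (-3.41) and the p53 target PERP (-3.37). Several of these belong to 1 clone of the gene. A separate PGLS clone stood at -0.52 and 0.87 at rounds 0 and 1, another of RABGAP1 at 0.45 and 0.01, and another of ARHGAP17 fell by 2.67. The other H19 clone fell as well, from 3.93 to 2.53. Of the 20 genes named, 11 had another tested clone, of which 2 were called in the same direction, 1 in the opposite one and 8 not called.

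In all, 735 of 5537 features (299 higher, 436 lower) passed at round 1, against 1868 (39 higher, 1829 lower) without centring and 1289 with all 16 arrays and a dye term. The 4 round 0 arrays have 3 decimals in every cell and none of the 12 amplified arrays does (83.2% to 88.2% of cells), so that a difference in processing and round 0 cannot be told apart. The count fell to 2 when only these 2 rounds were fitted, and it changed with every RNA left out. It was 191 and 150 without replicates 1 and K of round 0, 320 and 112 without those of round 1, 466 without either of round 2, 457 without either of round 3, and 346 without the round 1, replicate 1, Cy3 array.

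After 2 rounds CFL1 stood at 3.29 (log2 difference 4.80 ± 0.21, n = 2, adjusted p = 0.000899), GALT went from -3.93 to 0.14 (4.07 ± 0.32) and ECI2 from -2.10 to 1.51 (3.62 ± 0.28). The largest increase was 5.88 ± 1.13 for MBP (myelin basic protein, adjusted p = 0.0292), followed after CFL1 and GALT by the pseudokinase TRIB3 (3.79), HADHA (3.68), the semaphorin SEMA4B (3.64), SPPL2A (3.61), EFNA5 (3.51) and IRF2BP2 (3.39). PGLS (-4.97), SLC26A2 (-4.90), H19 (-4.39), the lymphoid transcription factor IKZF3 (-4.18) and RABGAP1 (-4.00) were lowest against round 0. IGFBP3 (-3.76), CAPN6 (-3.69), THAP4 (-3.53), the small heat shock protein HSPB1 (-3.49) and the PDZ protein GIPC2 (-3.34) followed. At round 0, other clones of MBP stood at 2.02 and 0.78 against -3.98 for the one named, and another of IKZF3 at -0.80 against 3.58. Of the 20 genes, 13 had another tested clone, 3 of which were called in the same direction and 10 not called.

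At round 2, 619 features (243 higher, 376 lower) passed, of which 414 were called in the same direction at round 1. Independent lists of these sizes would share 42.7, but both comparisons use the same round 0 RNAs. In 100 simulations of unchanged groups no feature was called in both, and the same numbers of features with the smallest p shared 211 on average and at most 256. These simulated groups shared their round 0 RNAs too, so the random spread of shared RNAs alone did not reach 414. A difference in the processing of round 0 would also be shared, and it was not simulated. The count was 67 without centring, 1244 with all 16 arrays and a dye term, 148 when only these rounds were fitted, 175 and 108 without replicates 1 and K of round 0, 24 and 53 without those of round 2, 375 without either of round 3 and 340 without the round 1, replicate 1, Cy3 array.

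After 3 rounds the same CFL1 and GALT features led the increases, at 4.71 ± 0.21 and 4.08 ± 0.32 (n = 2, adjusted p = 0.000757 and 0.00355). They were joined by the exonuclease REXO5 (3.89), WDR41 (3.62), the hyaluronan receptor CD44 (3.61), ECI2 (3.51), SPPL2A (3.42), EFNA5 (3.37), TRANK1 (3.16) and FMOD (3.09). The largest decrease was that of GPX3, the plasma glutathione peroxidase made mainly in kidney tubules, whose ratio was 6.62, 4.45, 3.48 and 1.57 at rounds 0 to 3 and fell by 5.05 ± 0.53 (adjusted p = 0.00775). GIPC2 took a like course, from 3.77 through 1.75 and 0.44 to -0.40, and so fell by 4.18. CAPN6 (-4.89, another clone of the gene), PGLS (-4.84), H19 (-4.52), STC1 (-3.75), IGFBP3 (-3.65), RABGAP1 (-3.61), CCDC186 (-3.41) and HSPB1 (-3.38) complete the 10. Of the 20 genes, 11 had another tested clone, 4 of which were called in the same direction and 7 not called. Another GALT clone went from -0.56 at round 0 to 0.50 at round 3 and was not called, while the one named stood at -3.93 at round 0. Another of ECI2 went from 1.73 to 3.24 and was called, while the one named stood at -2.10 at round 0.

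At round 3, 643 features (253 higher, 390 lower) passed, and 312 (114 higher, 198 lower) passed against round 0 at all 3 rounds in 1 direction, where the same numbers of smallest p in unchanged groups shared 101 on average. Of the features called at round 1, 2 and 3, 53.9%, 56.4% and 55.7% had a ratio nearer 0 than at round 0, against 49.6%, 51.9% and 52.4% of all features. The count was 130 (21 higher, 109 lower) without centring, 1322 with all 16 arrays and a dye term, 257 when only these rounds were fitted, 179 and 146 without replicates 1 and K of round 0, 381 without either of round 2, 146 and 103 without those of round 3, and 310 without the round 1, replicate 1, Cy3 array.

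**Figure D1:**
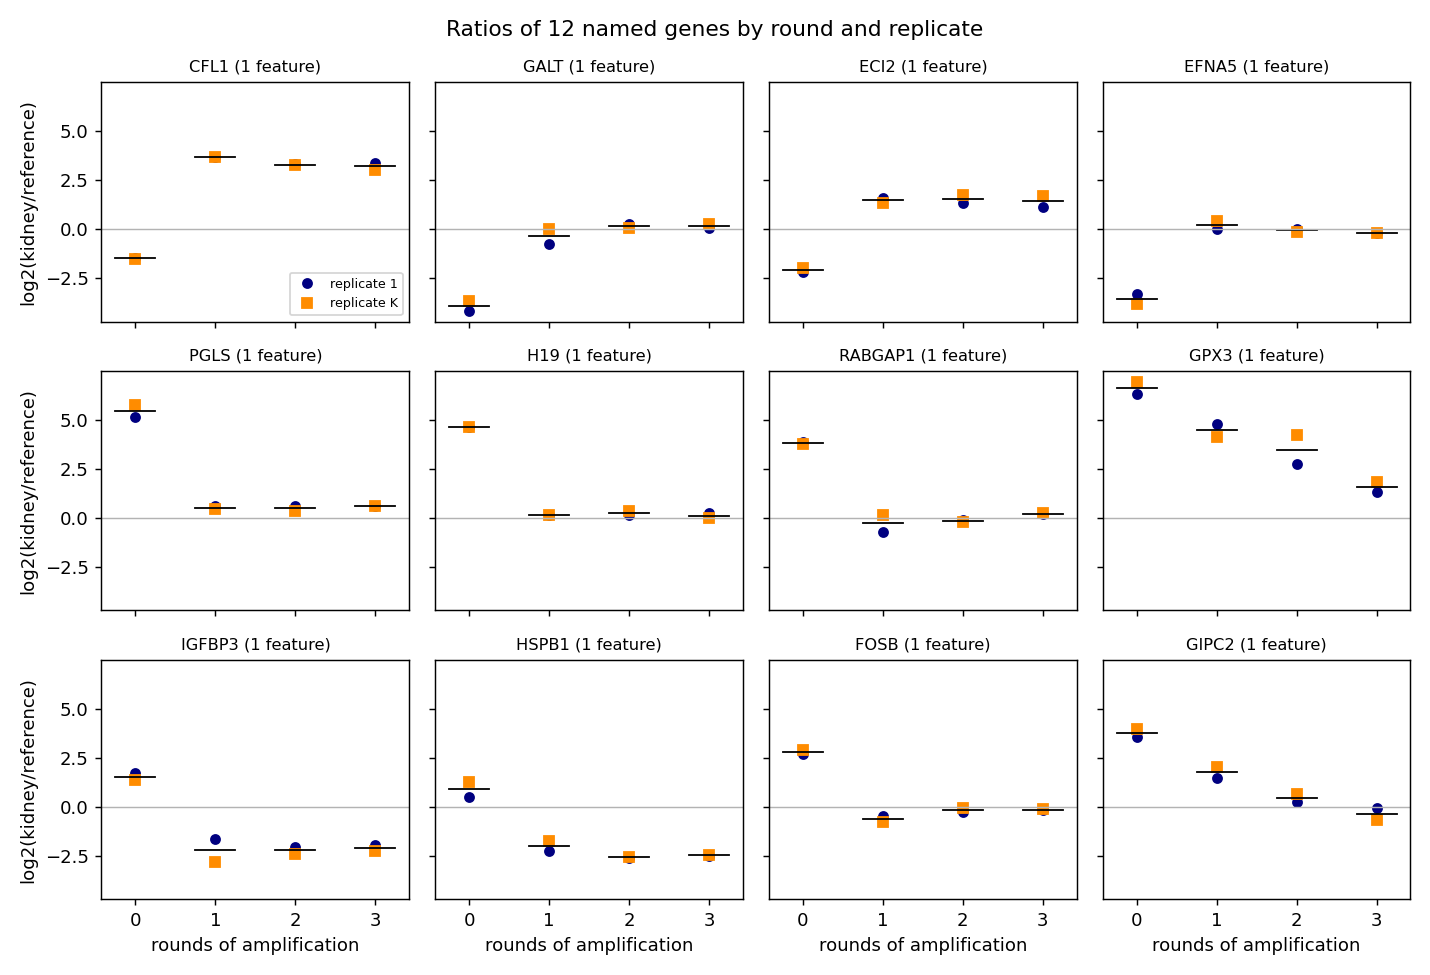
Log2 ratio of kidney over reference (vertical axis) by rounds of amplification (horizontal axis) for 12 named genes, 1 feature each; circles are replicate 1, squares replicate K and bars the mean of 2. CFL1 goes from -1.51 at round 0 to 3.66 at round 1, and GPX3 steps down from 6.62 to 1.57 at round 3.

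**Figure D2:**
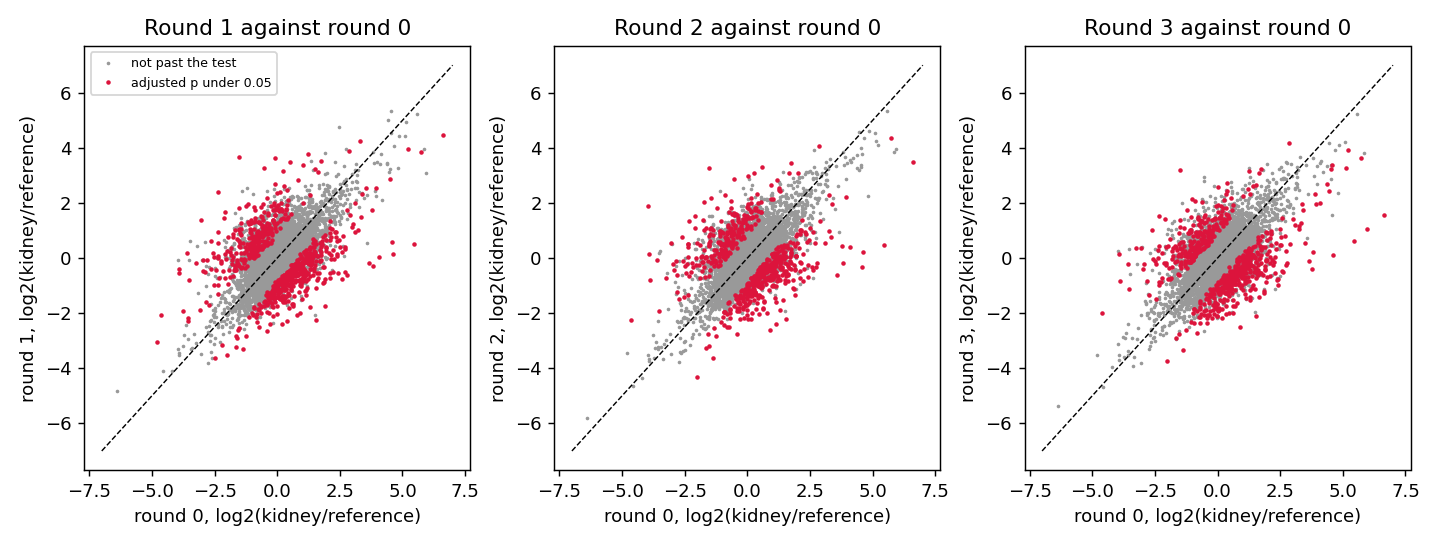
Mean log2 ratio at round 0 (horizontal axis) against that at rounds 1, 2 and 3 (vertical axes) for 5537 features; red points have an adjusted p under 0.05 and the dashed line marks equal ratios. The red points are 735, 619 and 643.

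Among the fixed lists, splicing factors and hnRNPs were lower at rounds 2 and 3: of 53 features, 10 fell and 2 rose at round 2, and 11 fell and 2 rose at round 3 (adjusted over the list alone, 15 and 4, then 14 and 3). camera gave an adjusted p of 0.0373 and 0.0305, against an adjusted p = 0.368 and 0.701 with an estimated correlation. SRSF1 fell by 1.69 and 1.94 and HNRNPU by 1.65 at round 2, while PRPF31 rose by 1.71 and 1.80. At round 1, 14 of the 53 fell and 1 rose (16 and 1 adjusted over the list alone), SRSF7 by 1.90 and HNRNPA2B1 by 1.72, but the list had an adjusted p of 0.0698. Without centring, the round 3 adjusted p was 0.0863.

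Immediate early and stress genes were lower at round 2, with 8 of 35 features down and 1 up (11 and 3 adjusted over the list alone), a camera adjusted p of 0.0373 and an adjusted p = 0.368 with an estimated correlation. FOSB fell by 2.97 and GADD45A, a growth arrest gene, by 2.25, while BTG1 rose by 1.89. At round 1, 8 fell and 1 rose (9 and 1 adjusted over the list alone), and at round 3, 5 fell and 3 rose, among them JUNB by 1.38 (8 and 3 adjusted over the list alone); the adjusted p was 0.207 and 0.0955. With arrays scaled to 1 median absolute deviation, the round 2 adjusted p was 0.059.

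Nuclear genes of oxidative phosphorylation (56 features) were higher as a group at rounds 2 and 3, by medians of 0.29 and 0.31. Without centring, their medians were 0.20 and -0.05, beside medians over all features of -0.08 and -0.34. camera gave an adjusted p of 0.0373 and 0.0305, an adjusted p = 0.736 and 0.750 with an estimated correlation, and 0.191 and 0.228 without centring. The list did not pass fry, with an adjusted p of 0.0588 and 0.0510. Few single features moved: 1 rose and 1 fell at rounds 1 and 2, and 2 rose and 1 fell at round 3, with 0 either way when adjusted over the list alone. They were UQCRC1 of complex III (1.28 at round 1), NDUFA8 of complex I (0.86 and 0.95 at rounds 2 and 3), ATP5F1B of the ATP synthase (1.14 at round 3) and, downward, NDUFA4L2 (-1.99, -1.88 and -1.73).

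The other 11 lists did not pass camera against round 0 at any round, with adjusted p from 0.0855 to 0.953. With fry, chaperones passed downward at rounds 1, 2 and 3 (adjusted p = 0.0177, 0.0350 and 0.0246). Reference and cytoskeleton genes passed fry upward at rounds 2 and 3 (0.0350 and 0.0312), the immune list upward at round 2 (0.0124) and the kidney list downward at round 3 (0.0427). Without centring, cytosolic ribosomal proteins passed downward at round 1 (adjusted p = 0.0186) and the immune list upward at round 2 (0.0472), but with an estimated correlation these had an adjusted p = 0.948 and 0.962 without centring, and 0.881 and 0.368 with centring. Of the kidney list, 5 features fell at round 1, and 4 fell and 1 rose at rounds 2 and 3. When adjusted over the list alone, 5, 6 and 5 fell and 2, 1 and 1 rose. GPX3 and CA12, a carbonic anhydrase (-2.13, -2.61 and -2.45), fell, and SLC27A2, a fatty acid transporter, rose by 1.41 and 1.43 at rounds 2 and 3. Of 48 placenta features, 5, 3 and 4 rose and 6, 4 and 4 fell at rounds 1, 2 and 3. Adjusted over the list alone, 5, 3 and 5 rose and 6, 6 and 4 fell. The growth factor IGF2 rose by 2.38 and the pregnancy-associated glycoprotein PAG11 by 2.12 at round 1. TFAP2C rose by 2.12 at round 3, and the imprinted PEG3 fell by 1.95, 2.06 and 2.48. The values given for list members are those of single clones: of the called genes that the naming rule takes from all lists at rounds 1, 2 and 3, 20, 16 and 16 had another tested clone, which was called in the same direction for 5, 2 and 2 and not called for the others.

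Of 31 immune features, IGHM alone rose at round 1 (1.07), and LCP1 (1.14) and the class II gene BOLA-DRA (2.41) at round 3, against 0 when adjusted over the list alone. At round 2 limma called 0 (9 at unadjusted p under 0.05), with LCP1 and BOLA-DRA at adjusted p of 0.0768 and 0.0691. Of 28 stroma features, 4, 2 and 2 rose and 4, 3 and 1 fell. When adjusted over the list alone, 6, 3 and 3 rose and 7, 5 and 2 fell. The collagen COL6A1 rose by 2.72, 1.71 and 2.14, TIMP1 by 1.74 at round 1, and TAGLN by 1.22 and 1.15 at rounds 2 and 3. MGP fell by 1.87, 1.38 and 2.10, fibronectin FN1 by 1.15 at round 1 and desmin DES by 1.59 at round 2. Signs differed between summaries for the stroma list, with a round 1 median of -0.13 and mean of 0.08, and with medians of 0.10 and 0.06 at rounds 2 and 3 beside a test direction of down. For the placenta list, medians at rounds 2 and 3 were 0.16 and 0.04 and means -0.08 and -0.04.

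Of 56 cytosolic ribosomal protein features, 3, 2 and 5 rose and 2, 0 and 2 fell at rounds 1, 2 and 3. Adjusted over the list alone, 1, 2 and 5 rose and 0, 0 and 2 fell. RPS10 rose by 1.47, 1.88 and 2.01 and RPL28 by 1.23, 1.09 and 1.25, while RPS24 and RPL6 fell at round 1 and RPS3A and RPL30 at round 3. Among 44 mitochondrial ribosomal features, MRPS34 alone rose, by 1.92 and 2.27 at rounds 2 and 3, and 3, 2 and 3 fell, such as MRPL51 by 1.72 and 1.09 at rounds 1 and 2. When adjusted over the list alone, 1, 1 and 2 rose and 1, 2 and 5 fell. For the proteasome (31 features), 1, 2 and 3 rose and 3, 1 and 2 fell. Adjusted over the list alone, 1, 2 and 4 rose and 3, 1 and 2 fell. PSMD8 rose by 1.57, 1.56 and 1.53, and PSMB4 fell at each round, by 1.44 at round 1 and 1.45 at round 3.

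Of 47 translation factor features, 1, 1 and 3 rose and 4, 3 and 3 fell at rounds 1, 2 and 3. When adjusted over the list alone, 1, 1 and 3 rose and 4, 2 and 3 fell. EIF4H rose by 2.30 at round 1, EEF1E1 by 1.38 and 1.55 at rounds 2 and 3 (-0.15 at round 2 with kidney in Cy5 only), and EIF4G3 fell by 1.26, 1.26 and 1.28. Of 52 chaperone features, 3, 2 and 1 rose and 8, 3 and 3 fell. Adjusted over the list alone, 4, 2 and 4 rose and 9, 3 and 9 fell. The mitochondrial HSPD1 rose by 2.78 at round 1, PDIA4 of the endoplasmic reticulum by 1.48 and 1.79 at rounds 2 and 3, and 1 of 4 HSPB1 clones fell at each round, while the other 3 were not called and 2 of them stood above their round 0 ratio. Of 9 histone features, H2AC20 rose by 0.95 at round 1 (-0.06 without centring), H1-2 fell by 1.33 and 0.98 at rounds 1 and 2, and limma called 0 at round 3 (4 at unadjusted p under 0.05), where H1-3 and H1-2 had the smallest adjusted p (0.0712 and 0.0921). When adjusted over the list alone, 1, 1 and 0 rose and 1, 1 and 0 fell. Of 14 reference and cytoskeleton features, CFL1 rose at each round and the tubulin TUBA1A by 2.56 at round 1, and none fell. Adjusted over the list alone, 2, 2 and 1 rose and 0, 1 and 0 fell.

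**Figure D3:**
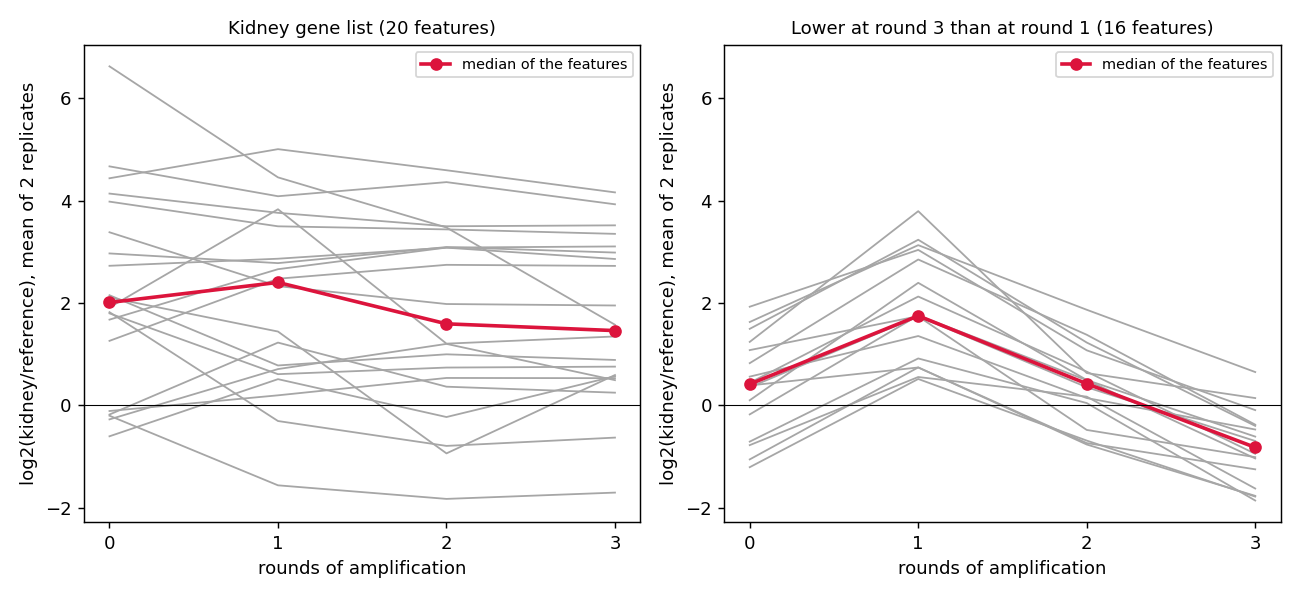
Log2 ratio of kidney over reference (vertical axes, mean of 2 replicates) by rounds of amplification (horizontal axes) for the kidney list and for the features lower at round 3 than at round 1; grey lines are features and red lines medians. The kidney list median is 2.01, 2.40, 1.59 and 1.46, and that of the falling features 0.41, 1.75, 0.42 and -0.82. For the kidney list, the median change per feature is -0.28 from round 0 to 1 and -0.15 from round 1 to 3.

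Round 3 against round 1 asks whether more amplification moved the ratios further. All 16 features past the test were lower at round 3 (2 higher and 14 lower with quantile normalization, and 0 called without centring). Each stood above 0 at round 1 and stepped down at rounds 2 and 3. The round 1 and round 3 values both took part in their selection, which favours such a course. PNRC2, a nuclear receptor coactivator, fell by 3.65 ± 0.36 (n = 2, adjusted p = 0.0216) from 3.79, the cargo protein TMED5 by 3.64 ± 0.43 (adjusted p = 0.0406) from 3.24, and the small GTPase RHOB by 3.23 ± 0.22 (adjusted p = 0.0145) from 2.85. The others were DDX17 (an RNA helicase), MAPK6, EIF4H, PPP1R15B, CAMK2G, CD2AP (an adaptor of the podocyte slit diaphragm), HSP90AA1, ABCD3 (a peroxisomal transporter), PPP1R12A, LOC783577, COPZ1, MCL1 (an inhibitor of apoptosis) and CNOT7, with falls from 3.13 to 1.83, and 10 of the 16 also passed as lower at round 3 than at round 0, while the other 6 were lower without passing. No feature passed upward, and the smallest p among those higher at round 3 were those of BDH2 (1.49, adjusted p = 0.0558), JAG2 (1.75, 0.0558) and ACSL5 (1.56, 0.059). Some of these values belong to 1 clone of the gene. Another PNRC2 clone stood at 0.93 and 0.43 at rounds 1 and 3, another of CAMK2G at -0.26 and -0.50, and another of ACSL5 at 0.59 and 0.53. The count was 0 with only these rounds fitted or with kidney in Cy3 alone, 526 (298 higher, 228 lower) with all 16 arrays and a dye term, and 232 (104 higher, 128 lower) for features with a value on every array. Without replicate 1 of round 1 or of round 3 it was 1 and 3, and without any other RNA 0.

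Between successive amplified rounds limma called 0 features. At unadjusted p under 0.05 there were 569 from round 1 to 2 and 401 from round 2 to 3, against 1176 from round 1 to 3. For the single steps the smallest adjusted p was 0.17 and 0.325. From round 1 to 2 the features with the smallest p were RNASEH1 (1.57), LOC514189 (1.67) and TOR1AIP2 (1.27) upward and ZDHHC20 (-2.09), PNRC2 (-3.16) and MCL1 (-1.48) downward. From round 2 to 3 they were LOC515150 (3.60), NUDT16L1 (2.48) and VDR, the vitamin D receptor (1.82), and RHOB (-1.76), CAMK2G (-1.90) and ZMYND8 (-2.05). With all 16 arrays and a dye term, 31 features passed from round 1 to 2, and without replicate 1 of round 1, 3. The F test over all 4 rounds called 420 features, against 6 and 4 without replicates 1 and K of round 0, 238 and 147 without those of round 1, 133 and 110 without those of round 2, 130 and 95 without those of round 3, and 177 without the round 1, replicate 1, Cy3 array.

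Across features, replicates of a round correlated at 0.757 on average (range 0.723 to 0.814), amplified rounds with each other at 0.689 (0.598 to 0.759) and round 0 with the amplified rounds at 0.520 (0.473 to 0.564). These are correlations across features, which are not independent replicates. The range of round 0 with the amplified rounds lay below both others, which overlapped each other. The SD of the ratios was 1.10, 1.07, 1.05 and 1.03 at rounds 0 to 3, and slopes on round 0 were 0.554, 0.560 and 0.527. With either dye orientation alone, the mean SD of the amplified rounds was not below that of round 0. The changes from round 0 to rounds 1 and 2 correlated at 0.802, against 0.498 in simulated unchanged groups that share the round 0 RNAs. When each change used another round 0 replicate, which removes that sharing, they correlated at 0.523. No simulation was run for that case, and 0.498 is not its chance level. The steps from round 0 to 1 and from 2 to 3, which share no array, correlated at -0.165, where simulated unchanged groups averaged 0.003. Dye swaps of 1 RNA correlated at 0.671 at round 0 and 0.457 (0.245 to 0.586) at rounds 1 to 3.

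**Figure D4:**
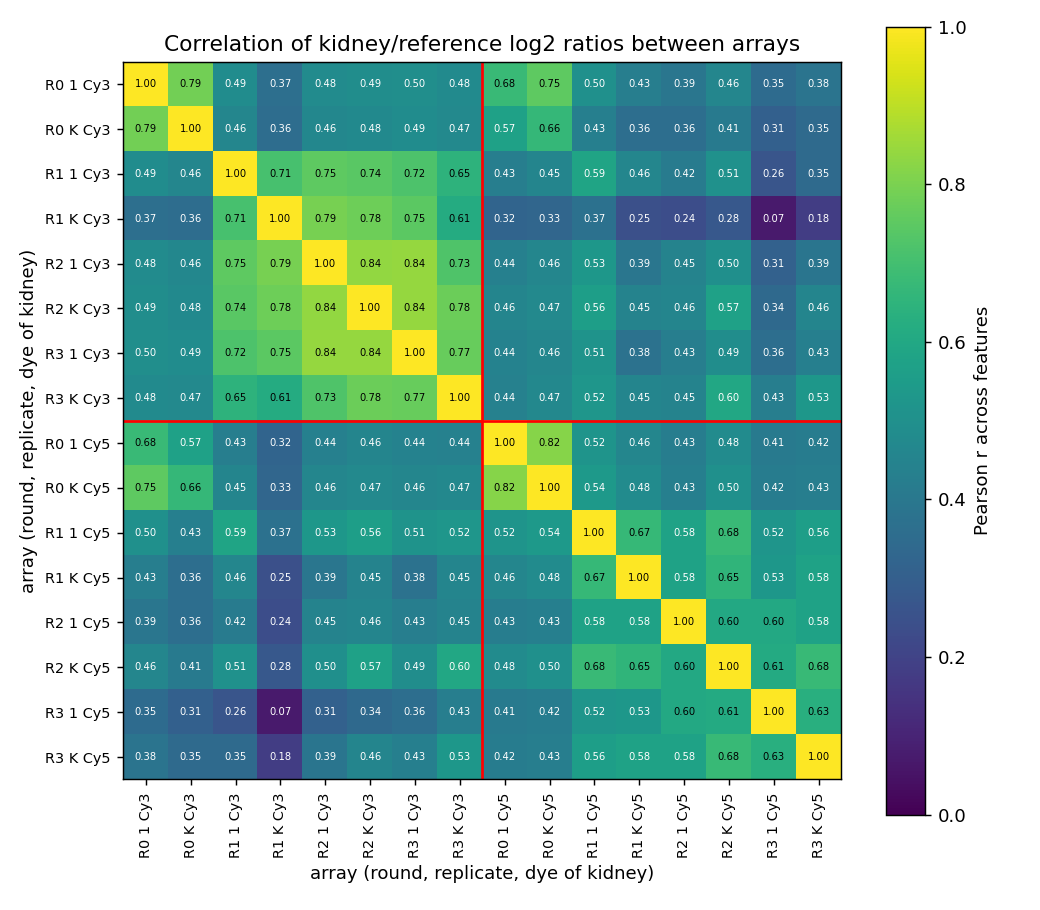
Pearson correlation across features between the 16 arrays (both axes; R0 to R3 are rounds, followed by replicate and kidney dye), with Cy3 arrays before the red lines and Cy5 arrays after them. Amplified arrays average 0.753 within Cy3, 0.603 within Cy5 and 0.415 across dyes.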

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

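The test of features without a listed gene was chosen after the results for the listed features were seen. Duplicate spots of the round 2, replicate 1, Cy5 array correlated at 0.541, against 0.792 to 0.838 on the other 3 arrays of that round, which puts it past Dixon's 95% limit. It was the only array past that limit in 20 groups compared, and chance puts about 1 in 20 groups past it. Each group held both dye orientations of 1 round. Other amplified arrays with kidney in Cy5 were low too, at 0.654 and 0.642 at round 1 and 0.603 and 0.639 at round 3. Those of round 0 stood at 0.780 and 0.868. Without round 2 replicate 1, the count of features changed between rounds 2 and 0 was 24 in place of 619, but it also fell to 53 without replicate K of that round and to 175 and 108 without replicates 1 and K of round 0, so the drop is not particular to this RNA.

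Features without a gene in the annotation were outside the comparisons and also held changes. Of 2470 such features with a value in every RNA, 141 differed at round 1 from round 0 (60 higher, 81 lower), 52 at round 2 (19 higher, 33 lower) and 100 at round 3 (40 higher, 60 lower). The round 3 count is 4.05% of them, against 11.6% of the features with a gene. Replicates of round 0 correlated at 0.586 across them, against 0.814 across the features with a gene. Control spots cannot be told from clones among them, and no explanation was tested.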

How the results depend on the processing

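Alternatives chosen after seeing the data were all spotted features, leaving out the round 1, replicate 1, Cy3 array, the features whose duplicate spots differ least, the rescalings of the gene lists, and an estimated correlation for the lists without centring. Counts are given in the order round 1, 2 and 3 against round 0, and then for other comparisons by name; the cause of a change was not tested unless stated. A fold change of at least 1.5, no filter on missing values, and a trended robust prior left every count and direction within a factor of 1.5. The F test over all rounds called 657 features with quantile normalization and 214 with a replicate block, whose counts against round 0 were 629, 521 and 567. Without centring, the median log2 difference over all features was -1.04, -0.08 and -0.34. The counts were then 1868 (39 higher, 1829 lower), 67 and 130, with 0 for round 3 against 1, 202 for the F test and 1222 for kidney against reference at round 3. With kidney in Cy3 only, the count was 391 at round 3 against 0 and 0 against round 1; with Cy5 only it was 207 and 252 at rounds 1 and 2, and 175 for the F test. All 16 arrays with a dye term gave 1289, 1244 and 1322, 31 for round 2 against 1, 526 for round 3 against 1 and 1587 for the F test. All 16 features lower at round 3 than at round 1 were called in that fit too. It used the same RNAs and took the 2 arrays of each as correlated values, not as 1 replicate. Its larger counts and shared calls are therefore no independent support. Fewer samples, only those of the rounds compared, gave 2, 148 and 257, 0 for round 3 against 1, and 1040, 1279 and 1036 for kidney against reference at rounds 1, 2 and 3. The stricter adjusted p of 0.01 gave 86, 63 and 89, 0 for round 3 against 1, 21 for the F test, and 1123, 1134, 1085 and 1038 for kidney against reference at rounds 0 to 3. Testing only the features above the median in mean ratio size gave 255, 284 and 288, 192 for the F test, 1301 for kidney against reference at round 0, and a correlation of round 0 with the amplified rounds of 0.578. Features with a value on all 16 arrays gave 1 call for round 2 against 1, 232 for round 3 against 1, 924 for the F test, and correlations of 0.859 within rounds, 0.621 from round 0 to the others and 0.787 among amplified rounds. The features whose duplicate spots differ least gave 7 for round 2 against 1, 1 for round 3 against 2, 392 (290 higher, 102 lower) for round 3 against 1, 1037 for the F test, and correlations of 0.913, 0.657 and 0.876. All spotted features gave correlations of 0.678, 0.439 and 0.614, and kidney in Cy3 only 0.797, 0.492 and 0.770; the Spearman correlation of round 0 with the others was 0.451. The SD of the amplified rounds minus that of round 0, -0.049, was -0.143 with arrays scaled to 1 median absolute deviation, 0.019 with Cy3 only and 0.025 with Cy5 only. Without the round 1, replicate 1, Cy3 array, the counts were 346, 340 and 310, and 177 for the F test. Leaving out each RNA in turn, where the lone RNA left in a round is assumed to vary like the others, gave 112 to 466, 24 to 537 and 103 to 542. It gave 0 to 3 for round 2 against 1 and for round 3 against 1, 4 to 238 for the F test, and 977 to 2153, 1161 to 2018, 861 to 1954 and 885 to 1917 for kidney against reference at rounds 0 to 3. The correlations stayed between 0.737 and 0.768 within rounds, 0.512 and 0.528 from round 0 to the others, and 0.663 and 0.705 among amplified rounds. Gene lists called at rounds 1, 2 and 3 numbered 0, 3 and 2 with camera, 0, 0 and 0 with an estimated correlation, 3, 5 and 5 with fry, 1, 3 and 0 without centring, 2, 2 and 2 with a replicate block (gaining splicing and cytosolic ribosomal proteins at round 1, both at adjusted p = 0.0456, or adjusted p = 0.907 with an estimated correlation, and losing immediate early and stress genes at round 2, 0.0645), 0, 2 and 2 with arrays scaled to 1 median absolute deviation, and 0, 3 and 2 with quantile normalization. Over the 191 results for named genes and their alternatives, 3396 kept their direction and side of the threshold, 1098 kept the direction but lost the call, 29 gained one and 4 reversed. Those 4 were BOLA-DRA (-0.35) and EEF1E1 (-0.15) at round 2 with kidney in Cy5 only, H2AC20 at round 1 without centring (-0.062) and H1-3 at round 3 with kidney in Cy3 only (0.84). Signal over background was not analysed here, so that the limit it sets on weak spots is unknown.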

Other observations

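The tests of a processing batch, of both explanations for the dye and of an offset of round 3 were chosen after the results were seen, as were the list tests between rounds 2 and 1 and those with an estimated correlation and no centring; those of weak spots, of accumulating change and of drift were set before. Between rounds 1 and 2, where limma called 0 single features (569 at unadjusted p under 0.05), some gene groups moved together. Features of oxidative phosphorylation had a median log2 difference of 0.22 and mitochondrial ribosomal proteins one of 0.31, both higher at round 2 under every scaling tried (camera adjusted p = 0.00526 and 0.0264). Both had an adjusted p = 0.542 with an estimated correlation and 0.207 with fry. Cytosolic ribosomal proteins had a median of 0.16 and an adjusted p of 0.0332, but an adjusted p = 0.747 with an estimated correlation, 0.605 with arrays scaled to 1 median absolute deviation and 0.272 with quantile normalization. Without centring, the median over all features was 0.96 between these rounds, and the placenta list passed camera too, lower relative to the other features (adjusted p = 0.0479, and adjusted p = 0.923 with an estimated correlation).

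Different cDNA clones of a gene gave related values. For 905 genes with at least 2 clones, the Spearman correlation between clones was 0.553 for the ratio at round 0, 0.393, 0.427 and 0.400 at rounds 1, 2 and 3, and 0.269 (95% bootstrap interval 0.202 to 0.328) for the change from round 0. Of 213 features called at round 3 that had another clone, 101 (47.4%, exact 95% interval 40.6% to 54.4%) lay farther from it at round 0 than at round 3. That interval treats the features as independent, which they are not, since all were measured on the same RNAs. Across 22 blocks of neighbouring features, round 0 correlated with the amplified mean at 0.488 to 0.723. The kidney list changed from round 1 to 3 by a median of -0.15, at percentile 83.4 of random lists matched on the round 1 ratio, whose median was -0.35.

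The first pattern is the set of features that differ between round 0 and the amplified rounds. Weak, noisy spots are not its whole source, since 23.9% of the 2769 features whose duplicate spots differ least changed, against 17.0% of the others. For change that accumulates with each round, the steps from round 0 to 1 and from round 2 to 3 correlated at -0.165, under the 0.1 set beforehand. Simulated unchanged groups reached at most 0.0734. Only 26.1% of the features called at round 1 moved further that way from round 2 to 3, and most moved back. Over these called features the 2 steps correlated at -0.390. Over all features, 40.4% had the same sign in both steps, against 50.0% in simulated unchanged groups. The first change thus did not carry on from round 2 to 3. The step from round 0 also holds any difference in processing and the unamplified kidney. It therefore cannot test build-up among the amplified rounds. There, 1176 features had an unadjusted limma p under 0.05 from round 1 to 3, against 569 and 401 for single steps. Means of rounds 1 and 3 correlated at 0.717, against 0.827 and 0.834 for neighbouring rounds, which leaves such build-up open. Round 0 arrays processed in another batch than the amplified ones cannot be told apart from an effect of amplification itself, because all 4 round 0 arrays and none of the 12 others share a number format. A change made mostly in the first amplification may account for the pattern as well, and the design tests no biological explanation, since all 8 RNAs are kidney.

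The second pattern is that arrays of opposite dye differ more after amplification. Random noise of single arrays as the only source of the disagreement is argued against. Amplified arrays of 1 dye orientation correlated better than arrays of opposite orientation by 0.263 on average (0.753 within Cy3 and 0.603 within Cy5, against 0.415 across). At round 0 there was a gap too (0.789 within Cy3 and 0.819 within Cy5, against 0.573 to 0.752 across), so this does not address the increase. Duplicate spots of Cy5 arrays correlated at 0.780 and 0.868 at round 0. At rounds 1, 2 and 3 they correlated at 0.654 and 0.642, 0.541 and 0.838, and 0.603 and 0.639. For Cy3 arrays the values were 0.793 and 0.730 at round 0 and 0.726 to 0.839 after amplification. Noise that grew with amplification was not tested as a source of the increase and stays open. A ratio bias that follows the dye and not the sample is a candidate explanation: the dye effect of a feature correlated between replicates at 0.431 to 0.522 in the 4 rounds. Since round 0 is among these (0.431), the correlations show a dye bias and do not test its increase. The SD of the dye effect was 0.483 at round 0 and 0.681, 0.584 and 0.619 at rounds 1, 2 and 3. The mean dye effect of round 0 correlated with that of the amplified rounds at 0.190. No biological explanation was tested, since the dyes were swapped on the same RNA.

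The third pattern is the 16 features that stepped down from round 1 to round 3, for which an offset of the round 3 arrays alone stays open. The 16 changed by a median of -1.47 from round 1 to 2 (range -3.16 to -0.38) and of -1.14 from round 2 to 3. However, they were picked in part for high round 1 and low round 3 values, which builds in a fall at both steps. A drift of features through successive rounds could account for them, but across all features the step from round 1 to 2 in 1 replicate correlated with the step from round 2 to 3 in the other at only 0.107 on average (0.084 and 0.129). These values lie on both sides of the 0.1 set beforehand for a drift and above the 0.05 set against it, which leaves it open. No biological explanation was tested.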
